A study of Mus musculus with 8 samples.

How the data were processed

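Gene expression was measured in splenic B cells of C57Bl/6 mice on 8 Affymetrix arrays. B1 cells were sorted as CD19+CD43+ and B2 cells as CD19+CD43-, from mice with induced deletion of Ikaros (Cre+) and from control mice (Cre-). The 4 groups, Cre+ B1, Cre- B1, Cre+ B2 and Cre- B2, held 2 arrays each, and each array was 1 column of the deposited table. Biotin-labelled double-strand cDNA had been made from 20 ng of total RNA per array with a whole-transcriptome amplification kit, so the strand of a transcript was not kept. The values deposited by the authors are log2 signals from RMA, which corrects background, applies quantile normalization across arrays and summarizes the probes of a probe set by median polish. Affymetrix Expression Console version 1.4.1 with RMA was used, per the submitters' processing notes; further details were not given in the sources used here. The values ran from 2.43 to 13.5, with array medians between 4.94 and 5.02. Detection calls were not used here. A group mean at or below the highest array median, 5.02, was therefore taken as not clearly above background, a limit set after the results were seen. A difference against such a group that passed is given as a lower bound, except in the interaction, where it bounds nothing.

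The table held 35556 probe sets. The probe table supplied with it listed 23410 of these, 21789 with 1 gene symbol and 1621 with several, and left 12146 unnamed. Of the probe sets with 1 symbol, 21698 had a gene identifier found in a reference table for the GRCm38.p6 assembly, and 0 symbols needed an update. That assembly served only for which genes neighbour each other, and no coordinates were taken from it. The 21789 probe sets named 19938 genes. A gene was represented by its probe set with the highest mean over the 8 arrays, and it was tested if it exceeded the array median on at least 2 arrays, which left 10871 genes. Where probe sets of a named gene disagreed in sign or by a large margin, the other value was given beside it.

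One linear model with the 4 groups was fitted to all 8 arrays in limma 3.58.1 (R 4.3.3), with moderated two-sided tests and Benjamini-Hochberg adjustment, and genes with an adjusted p below 0.05 were called. The fit had 4 residual and 4.24 prior degrees of freedom, and the median standard error of a log2 difference between groups was 0.11. A gene's spread was taken to be the same in all 4 groups. The 6 comparisons were Cre+ against Cre- in B1, Cre+ against Cre- in B2, B1 against B2 in control mice, B1 against B2 after deletion, the difference between the deletion effects (interaction), and the deletion effect averaged over both cell types in an additive model with 4 arrays per arm. No control array was shared between the deletion effects in B1 and in B2. Replicate 1 was female and replicate 2 male in every group, and the series describes 2 independent experiments, so that the replicate number, the experiment and the sex cannot be told apart. The replicate number was taken to tie the 4 arrays of an experiment together. Residuals of the 4 groups were checked for this over 10564 autosomal genes and correlated by 0.06 to 0.30 across genes, which are not independent replicates. A fit with the replicate as a block was therefore run as an alternative, and its value is given where it changed the call of a list or of a gene difference described, or moved a count by more than 1.5 times. Results were also split by experiment, with 1 array per group in each.

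Gene lists for the cell types, pathways and possible admixed cells were written out before the data were examined, as were the comparisons, thresholds, the rule for named genes and all the alternatives. The lists covered the Ikaros family, B1, follicular, marginal zone and plasma cell markers, endoplasmic reticulum chaperones, cell cycle, B cell receptor signalling, Toll-like receptor signalling, activation and immediate early genes, interferon-stimulated genes, and germinal centre genes. They further covered MHC class II presentation, immunoglobulin constant regions with J chain, immunoglobulin variable, diversity and joining segments, B cell progenitor genes, B cell lineage transcription factors, the Notch pathway, adhesion and cytoskeleton, and chemokine and lipid homing receptors. The rest were the BCL2 family, glycolysis, T cell, NK cell, myeloid, dendritic, erythroid and megakaryocyte markers, and ribosomal proteins. These made 29 lists with at least 3 tested members. A pattern for mitochondrial transcripts matched no gene, and sex-linked genes were used only to check the labels. The ribosomal list was made from a symbol pattern that also catches ribosomal S6 kinases and pseudogenes. Lists were tested against the other genes with camera in limma, with a preset inter-gene correlation of 0.01 and adjustment over the 29 lists of a comparison. The same test with a correlation estimated from the residuals, and the rotation test fry (statmod 1.5.0), were run as alternatives. Members were also adjusted over the list alone.

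Named genes were, for each deletion effect and for control B1 against B2, up to 8 per direction with the largest log2 change among those called whose arrays did not overlap between the groups, and 4 per direction in the other comparisons. Places left over went to the genes of lowest unadjusted p with a log2 change of at least 1, given as not passing. Immunoglobulin segments, predicted genes and small RNA genes took no place. Members of the Ikaros family were always given, with up to 4 members of each list described, and Spn (CD43) as a check of the sort. Other genes singled out in the text were chosen after their values were seen, which is said where they appear.

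Alternatives were no filter on dim probe sets, a filter at the 75th percentile, quantile normalization applied again, centring of each array on its median, use of all probe sets, the mean of a gene's probe sets, a variance prior with a trend, a robust prior, the replicate block, array weights, a fit of only the 4 arrays compared, and leaving out each array in turn. Without 1 array a group holds 1 array, which is then assumed to vary like the other groups. The fit was tested on simulated data of 10871 genes with the spread of these arrays. In the simulated deletion effects in B1 and in B2, 35.9% of genes changed by 0.5 on the log2 scale were called, 97.0% of those changed by 1 and 97.1% of those changed by 2, and 4.32% (B1) and 4.91% (B2) of the calls were false. In the simulated comparison of control B1 with B2 these shares were 48.4%, 95.5% and 98.6%, with 1.21% false calls. All 10 of 100 simulated lists of 20 genes that were shifted by 0.3 were called, with 0 false calls. The simulated errors were independent between genes, and the lists were drawn at random. This run therefore does not test the preset inter-gene correlation, on which the list calls depend.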

Results

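The data set held 8 arrays of sorted splenic B cells, with 2 arrays in each of 4 groups: B1 and B2 cells in which Ikaros had been deleted by induction (labelled Cre+) and their controls (labelled Cre-). B1 cells are the innate-like B cells that secrete natural IgM, and B2 cells are the conventional follicular and marginal zone B cells. Ikaros, encoded by Ikzf1, is a zinc finger transcription factor of lymphoid cells. Values were log2 RMA signals with array medians of 4.94 to 5.02. Where 1 or more of the groups compared had a mean at or below 5.02, a difference that passed is a lower bound and is given as at least the measured size. Replicate arrays of a group correlated at 0.992 to 0.995 across all 35556 probe sets. Over the 10871 tested genes the standard deviation of their log2 difference was 0.26 in Cre+ B1, 0.21 in Cre- B1, 0.25 in Cre+ B2 and 0.18 in Cre- B2. Transcripts that mark the sort and the sex matched the labels on every array. Spn, which encodes CD43, had log2 signals of 8.16 to 8.47 in B1 and 6.11 to 6.77 in B2. Xist, the transcript that silences an X chromosome, lay at 10.03 to 10.35 on the replicate 1 arrays, all female, and at 3.53 to 3.88 on the replicate 2 arrays, all male.

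Ikzf1 signal was higher on the arrays labelled Cre+ in both cell types. Its mean was 10.72 ± 0.23 (SD, n = 2) in Cre+ B1 and 10.04 ± 0.03 in Cre- B1. In B2 cells it was 10.46 ± 0.07 with Cre and 9.95 ± 0.03 without. In B1 cells it rose by a log2 change of 0.67 (SE 0.11, adjusted p = 0.0189), with 0.49 and 0.86 in the separate experiments. In B2 cells the log2 difference was 0.51 (SE 0.11, adjusted p = 0.122), with 0.54 and 0.49, and it did not pass. Averaged over both cell types Ikzf1 rose by 0.59 (SE 0.08, adjusted p = 0.00543). The labels do not say which part of the gene is removed, and where the probes of its 1 probe set lie was not checked, so these values do not measure the deletion. Without Cre- B1 replicate 1 or 2 the rise in B1 was 0.69 (adjusted p = 0.0998) or 0.65 (adjusted p = 0.111). The relatives Ikzf3, Ikzf4 and Ikzf5, which encode Aiolos, Eos and Pegasus, differed by -0.04, 0.06 and 0.02 in B1 and by -0.11, 0.08 and 0.04 in B2. None of them passed, and a second probe set of Ikzf5 gave -0.33 in B1 and -0.14 in B2.

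**Figure D1:**
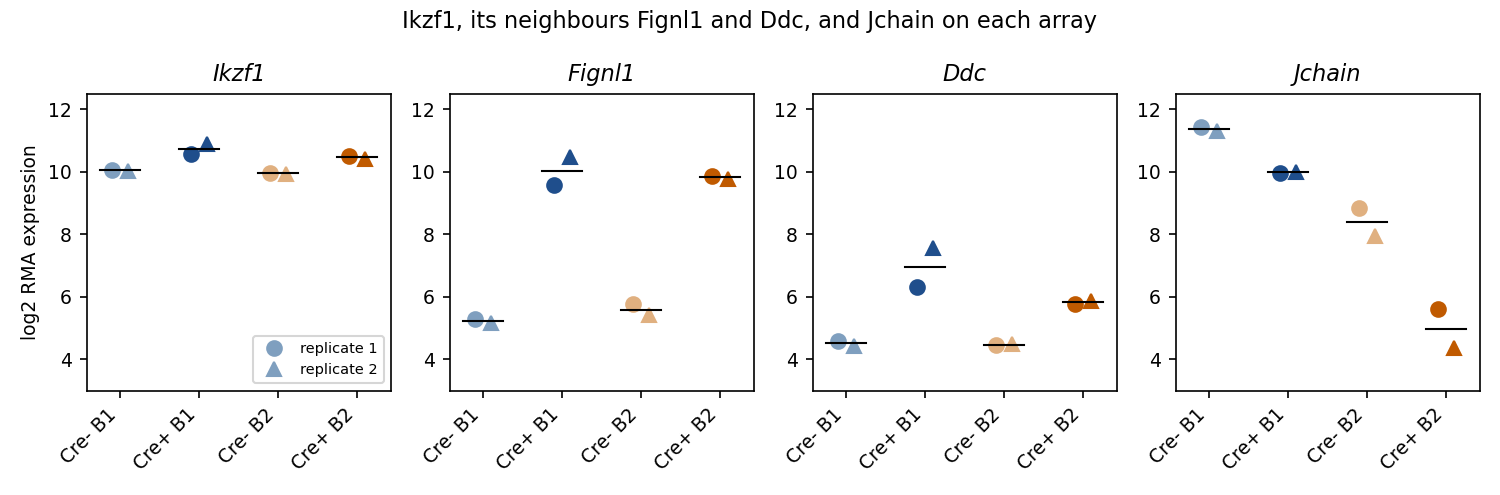
Log2 RMA expression (vertical axis) of Ikzf1, its neighbours Fignl1 and Ddc, and Jchain in the 4 groups; circles are replicate 1, triangles replicate 2 and bars the mean of 2 arrays. Fignl1 lay at 9.57 to 10.47 on the arrays labelled Cre+ and at 5.15 to 5.75 on the others, while Jchain fell to a mean of 4.98 in Cre+ B2.

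The first comparison asked how gene expression in Cre+ B1 cells differed from that in Cre- B1 cells. The term deletion effect stands for Cre+ minus Cre- throughout. The groups also differ in Cre itself, and the labels do not say whether the controls carried the same Ikzf1 allele. Loss of Ikaros and these other differences cannot be told apart here. Each array averages over all cells of a sort. A change within cells and a change in the share of B cell subsets cannot be told apart either. The strongest rise was in Fignl1, a neighbour of Ikzf1 that encodes an ATPase of DNA repair, with a log2 change of 4.80 (SE 0.25, 27.8-fold, n = 2 per group, adjusted p = 0.000199). Ddc, the next gene on that side, which encodes aromatic amino acid decarboxylase, rose by at least 2.43 (SE 0.31), by 1.73 and 3.13 in the separate experiments, from a level of 4.51 that lay below the array medians. Tmem176b and Tmem176a, which encode ion channels of intracellular vesicles, rose by 2.86 (SE 0.16) and 2.70 (SE 0.12). Aif1, an actin-binding protein of macrophages, rose by 2.47 (SE 0.29). Cd36, a scavenger receptor for lipids, rose by 2.38 (SE 0.17), and Ccl22, a chemokine that attracts CCR4-bearing T cells, by 2.19 (SE 0.14). Ifitm3, an antiviral membrane protein induced by interferon, rose by 2.52 (SE 0.39). Falls were measured in Myo1f, a myosin of immune cells, at -1.76 (SE 0.16), in the cytotoxic granule protease Gzma at -1.73 (SE 0.30) and in Sspn, a partner of the dystrophin complex, at -1.67 (SE 0.24). Dapl1 (by at least 1.55, SE 0.15, to 4.97), the innate defence protein genes Pglyrp1 (-1.44, SE 0.22) and Prg2 (-1.41, SE 0.12), Parm1 (-1.39, SE 0.13) and the T and NK cell surface protein gene Cd7 (-1.14, SE 0.24) fell as well. All adjusted p values of these genes lay between 0.000145 and 0.0396.

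Interferon-stimulated genes rose together in Cre+ B1 cells, with a median log2 change of 0.70 (adjusted p = 2.2e-07, adjusted p = 0.494 with an estimated correlation). Of 23 measured members 22 were positive, 4 were called higher and 11 when adjusted over the list alone. Among them Ifih1, a sensor of viral RNA, rose by 1.22 (SE 0.18; without Cre- B1 replicate 2 adjusted p = 0.0909). Oas2, an antiviral synthetase, differed by 1.90 (SE 0.45, adjusted p = 0.0546), and passed with the replicate as a block (adjusted p = 0.00384) or without Cre+ B1 replicate 1 (adjusted p = 0.0170). The list median was 0.28 in experiment 1 and 1.15 in experiment 2. It was 1.23 without Cre+ B1 replicate 1 or 0.24 without Cre+ B1 replicate 2, with the call kept. B cell progenitor genes rose with a median of 0.76 (adjusted p = 3.0e-06, adjusted p = 0.368 with an estimated correlation), 1.02 and 0.36 by experiment. Of its 10 members 3 were called higher, and 7 adjusted over the list alone. These included Bst1, a surface enzyme of early B cells, at no less than 1.25 (SE 0.15, from 4.38; without Cre- B1 replicate 1 adjusted p = 0.0568), and the stem cell factor receptor Kit at no less than 1.02 (SE 0.09, from 4.61). The surrogate light chain gene Vpreb1 differed by 1.66 (SE 0.55, adjusted p = 0.144), and passed with the block (adjusted p = 0.0363) or without Cre+ B1 replicate 2 (adjusted p = 0.00909). Cell cycle genes rose with a median of 0.40 (adjusted p = 3.0e-06, adjusted p = 0.457 with an estimated correlation), and 30 of 31 were positive. Of these 4 were called higher and 1 lower, and 15 and 1 adjusted over the list alone. Tyms, which makes thymidylate for DNA synthesis, rose by 0.95 (SE 0.17), though not without Cre+ B1 replicate 1 (adjusted p = 0.0743) or Cre- B1 replicate 1 or 2 (adjusted p = 0.136 and 0.0994). Ccne1, which encodes cyclin E1, fell by 0.85 (SE 0.09). The list medians were 0.26 and 0.53 by experiment, and 0.24 without Cre+ B1 replicate 2. Marginal zone markers rose with a median of 0.15 (adjusted p = 0.000191, adjusted p = 0.421 with an estimated correlation), 0.24 and 0.22 by experiment and 0.31 without Cre+ B1 replicate 1. Of 17 members 3 were called higher, and 6 higher and 1 lower adjusted over the list alone. Besides Cd36 they included Cd1d1, which presents lipids to NKT cells, at 1.30 (SE 0.19; without Cre- B1 replicate 2 adjusted p = 0.0811).

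Plasma cell markers fell in Cre+ B1 cells, with a median of -0.34 (adjusted p = 0.000579, adjusted p = 0.421 with an estimated correlation), -0.35 and -0.28 by experiment. Of 18 members 3 were called lower, and 1 was higher and 9 lower adjusted over the list alone. Prdm1, which encodes the plasma cell regulator Blimp-1, fell by 0.92 (SE 0.14; without Cre- B1 replicate 1 adjusted p = 0.0928). Jchain, which joins IgM and IgA into polymers, differed by -1.38 (SE 0.38, adjusted p = 0.0902), and passed with the replicate as a block (adjusted p = 0.0303) or without Cre+ B2 replicate 1 or 2 (adjusted p = 0.0259 for each). B1 cell markers fell with a median of -0.22 (adjusted p = 0.00716, adjusted p = 0.542 with an estimated correlation), -0.14 and -0.36 by experiment. Of 22 members only Il5ra, the interleukin 5 receptor chain, was called, at -0.97 (SE 0.18), and 4 were lower adjusted over the list alone. Il5ra was not called without Cre- B1 replicate 1 or 2 (adjusted p = 0.148 and 0.123) or Cre- B2 replicate 1 or 2 (adjusted p = 0.0520 for each). The list call was lost without Cre- B1 replicate 1 (adjusted p = 0.0523) or Cre+ B1 replicate 2 (adjusted p = 0.243, median -0.10). Its median was -0.35 without Cre+ B1 replicate 1. Follicular markers fell with a median of -0.14 (adjusted p = 0.0478, adjusted p = 0.537 with an estimated correlation), and centring each array on its median ended the call (adjusted p = 0.0571). Of 15 members Fcer2a, the low-affinity IgE receptor CD23, fell by 1.02 (SE 0.08), while 2 members were called higher. Adjusted over the list alone 2 were higher and 5 lower. The follicular list call was lost without Cre+ B1 replicate 1 (adjusted p = 0.150), Cre- B1 replicate 1 (0.205), either Cre+ B2 array (0.0563) or either Cre- B2 array (0.0579). Its median was -0.22 without Cre- B1 replicate 2. Ribosomal protein genes had a median of 0.07 (adjusted p = 0.0478, adjusted p = 0.494 with an estimated correlation), with 0 of 63 called by limma, 4 at an unadjusted p below 0.05, and 0 adjusted over the list alone. Their call was lost with the replicate as a block (adjusted p = 0.0749) and with quantile normalization applied again (adjusted p = 0.644). It was also lost without Cre+ B1 replicate 1 or 2 (adjusted p = 0.117 and 0.139), Cre- B1 replicate 1 (0.128), either Cre+ B2 array (0.0697) or either Cre- B2 array (0.0677).

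Markers of T and NK cells were lower in the same arrays. Cd28, which differed by -1.03 (SE 0.31), is a listed marker of both T and plasma cells. Ctla4 is a listed marker of both T and B1 cells. Part of the falls of the plasma and B1 lists, here and averaged, may therefore come from the T cell signal. The 20 T cell markers had a median of -0.32 (adjusted p = 3.7e-09, adjusted p = 0.285 with an estimated correlation), -0.38 and -0.37 by experiment, and 0 of them were positive. Of these 5 were called lower and 10 adjusted over the list alone, among them Cd3g, a chain of the T cell receptor complex, at -0.93 (SE 0.14; without Cre- B1 replicate 1 adjusted p = 0.0850) and the T cell kinase Prkcq at -0.95 (SE 0.12). The 7 NK cell markers had a median of -0.73 (adjusted p = 0.000105, adjusted p = 0.421 with an estimated correlation), -0.69 and -0.89 by experiment and -1.10 without Cre- B1 replicate 1, with 2 called lower and 6 adjusted over the list alone. The 17 myeloid markers had a median of -0.24 (adjusted p = 0.255), with 0 called by limma, 2 lower at an unadjusted p below 0.05, and 0 adjusted over the list alone. Toll-like receptor signalling (median 0.09, adjusted p = 0.0516) and megakaryocyte and platelet markers (median 0.11, adjusted p = 0.129) passed with the replicate as a block (adjusted p = 0.0493 and 0.0404). In limma 467 genes changed in B1 cells, 296 higher and 171 lower, and 91 of them changed more than 2-fold, 73 higher and 18 lower. With each array centred on its median the counts were 322 higher and 108 lower, so the share higher was 74.9% in place of 63.4%. The differences of the experiments correlated at 0.571 across all genes, which are not independent replicates. With all probe sets, named or not, 125 features were called. Without Cre- B1 replicate 1 or 2 only 111 or 109 genes were called, and 256 without Cre- B2 replicate 1 and 256 without replicate 2. Of the 16 genes named first 11 were called whichever array was left out. Calls were lost without Cre- B1 replicate 1 for Ifitm3, Ddc, Pglyrp1 and Cd7 (adjusted p = 0.103, 0.0549, 0.0952 and 0.107) and without Cre- B1 replicate 2 for Ddc, Gzma, Pglyrp1 and Cd7 (adjusted p = 0.0652, 0.0691, 0.0717 and 0.214). They were also lost without Cre+ B1 replicate 1 for Gzma and Cd7 (adjusted p = 0.0844 and 0.0654), without Cre+ B1 replicate 2 for Ifitm3 (adjusted p = 0.0558), and without any B2 array for Cd7 (adjusted p = 0.0544 for each Cre+ and 0.0740 for each Cre- array).

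In B2 cells the question was the same. Fignl1 rose again by 4.23 (SE 0.25, 18.8-fold, n = 2 per group, adjusted p = 0.0013). Alox5ap, needed for leukotriene synthesis, rose by 2.21 (SE 0.23), Tmem176b by 1.81 (SE 0.16) and Tmem176a by at least 1.45 (SE 0.12, from 4.98). Lxn, an inhibitor of carboxypeptidases, rose by 1.51 (SE 0.20), Nlrc5, a transactivator of MHC class I genes, by 1.24 (SE 0.12; 0.37 to 1.27 over its 19 probe sets), Zfp385a by 1.11 (SE 0.11) and Dnase1l3, a nuclease that digests chromatin outside cells, by 1.10 (SE 0.16). The strongest fall was in Jchain, from a mean log2 signal of 8.39 ± 0.62 (SD, n = 2) to 4.98 ± 0.87, a fall of at least 3.41 (SE 0.38, adjusted p = 0.0135). Rgs13, a brake on chemokine receptor signalling in germinal centre B cells, fell by at least 2.76 (SE 0.24) to 4.11, and Il5ra fell by 1.49 (SE 0.18). The inhibitory receptor gene Pirb (-1.20, SE 0.14), Ms4a7 (-0.87, SE 0.12), Tmem71 (-0.76, SE 0.10), Endou, an RNA-cleaving enzyme (by at least 0.74, SE 0.10, to 4.97), and Lgals3, which encodes galectin 3 (-0.73, SE 0.08), fell as well.

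Interferon-stimulated genes rose in B2 cells with a median of 0.57 (adjusted p = 5.4e-10, adjusted p = 0.403 with an estimated correlation), 0.32 and 0.83 by experiment and 0.28 without Cre+ B2 replicate 2, and 22 of 23 were positive. Over all genes limma called 0 members, with 13 higher at an unadjusted p below 0.05, and 5 were higher adjusted over the list alone. Oas2 differed by 1.56 (SE 0.45, adjusted p = 0.232; with the replicate as a block 0.0257) and Oasl2 by 1.37 (SE 0.38, adjusted p = 0.226). Germinal centre genes fell with a median of -0.22 (adjusted p = 2.9e-07, adjusted p = 0.369 with an estimated correlation), -0.33 and -0.23 by experiment and -0.36 without Cre- B2 replicate 1, with Rgs13 called of 11 and 5 lower adjusted over the list alone. Bcl6, the germinal centre regulator, differed by -0.52 (SE 0.15, adjusted p = 0.247). Whether expression fell within cells or the sort held fewer germinal centre or plasma cells was not measured, here and for Jchain. Plasma cell markers fell with a median of -0.08 and a mean of -0.39 (adjusted p = 0.000216, adjusted p = 0.403 with an estimated correlation), with only Jchain called of 18 and 7 lower adjusted over the list alone. Their medians were -0.12 and -0.11 by experiment. They were -0.21 and -0.04 without Cre+ B2 replicate 1 and 2, and -0.05 and -0.16 without Cre- B2 replicate 1 and 2, with the call kept. Immunoglobulin constant regions and J chain fell with a median of -0.20 (adjusted p = 0.000821, adjusted p = 0.369 with an estimated correlation), -0.35 and -0.12 by experiment and -0.11 without Cre+ B2 replicate 1. Of the 4 members only Jchain was called, also adjusted over the list alone, and Ighm, the IgM heavy chain, differed by -0.10 (SE 0.12, adjusted p = 0.902). Igha and Ighg3 differed by -0.13 (SE 0.10) and -0.28 (SE 0.37). Jchain is in the plasma cell list too, so the calls of these lists are not independent. Follicular markers fell with a median of -0.20 (adjusted p = 0.00425, adjusted p = 0.403 with an estimated correlation), with 0 of 15 called by limma, 8 at an unadjusted p below 0.05, and 1 higher and 5 lower adjusted over the list alone. Their medians were -0.26 and -0.13 by experiment, and the call was lost without Cre- B2 replicate 1 (adjusted p = 0.0543) or Cre+ B2 replicate 2 (adjusted p = 0.158).

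Smaller shifts in B2 cells were called in 4 further lists, with 0 members called by limma over all genes. Endoplasmic reticulum chaperones fell with a median of -0.10 (adjusted p = 0.0403, adjusted p = 0.403 with an estimated correlation), -0.09 and -0.12 by experiment, with 5 of 25 at an unadjusted p below 0.05 and 0 adjusted over the list alone. Their call was lost with quantile normalization applied again (adjusted p = 0.0757), without Cre+ B2 replicate 1 or 2 (adjusted p = 0.0724 and 0.158, the latter with a median of -0.06) and without Cre- B2 replicate 1 or 2 (adjusted p = 0.0553 and 0.0868). Cell cycle genes had a median of -0.12 (adjusted p = 0.0274, adjusted p = 0.647 with an estimated correlation), -0.23 in experiment 1 and 0.02 in experiment 2, with 6 of 31 at an unadjusted p below 0.05 and 1 lower adjusted over the list alone. Without Cre- B2 replicate 1 their median was 0.03 (adjusted p = 0.872), without Cre- B2 replicate 2 it was -0.23. The call was also lost without Cre+ B2 replicate 2 (adjusted p = 0.123). Glycolysis genes rose with a median of 0.06 (adjusted p = 0.0403, adjusted p = 0.369 with an estimated correlation), 0.08 and 0.07 by experiment, with 5 of 16 at an unadjusted p below 0.05. Only the kinase gene Pdk1 was higher adjusted over the list alone, at 0.59 (SE 0.12; over all genes adjusted p = 0.105, with the block 0.0339). The glycolysis call was lost without Cre+ B2 replicate 1 or 2 (adjusted p = 0.0724 and 0.123), Cre- B2 replicate 1 (0.105) or either Cre+ B1 array (0.0562). The Notch pathway was called up (adjusted p = 0.0499, adjusted p = 0.403 with an estimated correlation) with a median of -0.02 but a mean of 0.12, and 4 of 11 were higher adjusted over the list alone, 5 at an unadjusted p below 0.05. Its medians were 0.03 and -0.03 by experiment, and -0.06 to 0.03 without 1 B2 array. Among its members the receptor gene Notch1 differed by 0.59 (SE 0.17, adjusted p = 0.250) and its target Hes1 by 0.48 (SE 0.08, adjusted p = 0.0617), and the list call was lost with quantile normalization applied again (adjusted p = 0.0553). It was also lost without Cre+ B2 replicate 1 or 2 (adjusted p = 0.0724 and 0.169), Cre- B2 replicate 1 (0.256) or either Cre- B1 array (0.0744).

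Markers of other cells shifted beside these changes. Myeloid markers fell in Cre+ B2 with a median of -0.56 (adjusted p = 0.00283, adjusted p = 0.403 with an estimated correlation), -0.99 in experiment 1 and -0.14 in experiment 2. The median was -0.05 or -1.17 without Cre+ B2 replicate 1 or 2 and -0.87 without Cre- B2 replicate 1, with the call kept. Of 17 members 0 were called by limma, 4 were at an unadjusted p below 0.05, and 2 were lower adjusted over the list alone. Megakaryocyte and platelet markers rose with a median of 0.24 (adjusted p = 0.000509, adjusted p = 0.369 with an estimated correlation), 0.27 and 0.22 by experiment, with 0 of 6 called by limma, 4 at an unadjusted p below 0.05, and 4 adjusted over the list alone. The platelet chemokine genes Ppbp and Pf4 differed by 1.47 (SE 0.46, adjusted p = 0.282) and 1.32 (SE 0.24, adjusted p = 0.0695; 4.54 in Cre- B2), and passed with the replicate as a block (adjusted p = 0.0455 and 0.0277), Pf4 also without Cre+ B2 replicate 1 (adjusted p = 0.00886). Immunoglobulin variable, diversity and joining segments had a median of -0.15 (adjusted p = 0.0521), and passed with the block (adjusted p = 0.0466). Dendritic markers had a median of 0.37 and did not pass in camera (adjusted p = 0.0632), but did with each array centred on its median (adjusted p = 0.0393). T cell and NK cell markers had medians of -0.02 (adjusted p = 0.453) and -0.04 (adjusted p = 0.939), and none passed over all genes; the NK list had a mean of 0.02. A fall could not be measured for 12 of the 20 T cell and 4 of the 7 NK cell markers, which lay at or below 5.02 in both B2 groups. In limma 38 genes changed in B2 cells, 29 higher and 9 lower, 14 of them more than 2-fold, and the differences of the experiments correlated at 0.512 across all genes. With the replicate as a block 91 genes were called, including all 38. With all probe sets, named or not, limma called 0 features (1498 at an unadjusted p below 0.05), and Fignl1 had an adjusted p of 0.0578. Without Cre- B2 replicate 1 or 2 only 1 or 2 genes were called, 23 without Cre- B1 replicate 1 and 23 without replicate 2, and 78 without Cre+ B2 replicate 2. Of the 16 genes named first Fignl1 alone was called whichever array was left out. The other 15 lost their calls without Cre- B2 replicate 1 (adjusted p from 0.0604 for Lxn to 0.267 for Ms4a7) and without Cre- B2 replicate 2 (0.0523 for Jchain to 0.208 for Dnase1l3). Further calls were lost without Cre+ B2 replicate 1 (Lxn, Pirb, Tmem71, Endou, Lgals3; 0.123 at most, for Tmem71), Cre+ B2 replicate 2 (Lxn, Dnase1l3, Ms4a7, Endou; 0.0787 at most, for Ms4a7), either Cre- B1 array (Lxn, Dnase1l3, Il5ra, Ms4a7, Tmem71, Endou; 0.0811 at most, for Dnase1l3) and either Cre+ B1 array (Dnase1l3, Ms4a7; 0.0563).

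The responses of the cell types overlapped. Both called 24 genes higher where 0.790 would be shared by independent draws, and 7 lower where 0.142 would be, with 0 in opposite directions. Both comparisons used the same estimate of each gene's spread, so independent draws can understate the overlap that arises without a shared response. Fignl1 rose by 4.80 in B1 and 4.23 in B2 (SE 0.25 each), Tmem176b, of myeloid cell vesicles, by 2.86 and 1.81 (SE 0.16), and its neighbour Tmem176a by 2.70 and at least 1.45 (SE 0.12). Rgs13 fell by at least 1.14, to 4.37, and at least 2.76, to 4.11 (SE 0.24), and Il5ra, which conveys the interleukin 5 signal to B1 cells, fell by 0.97 and 1.49 (SE 0.18). Of the 296 genes higher in B1, 268 (90.5%) were higher in B2 too, with a median of 0.67 in B1 and 0.32 in B2. Of the 171 lower in B1, 155 (90.6%) were lower in B2, with medians of -0.59 and -0.30. These genes were picked by their call in B1, which favours large B1 values. The smaller medians in B2 therefore do not show that the response was weaker there.

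**Figure D2:**
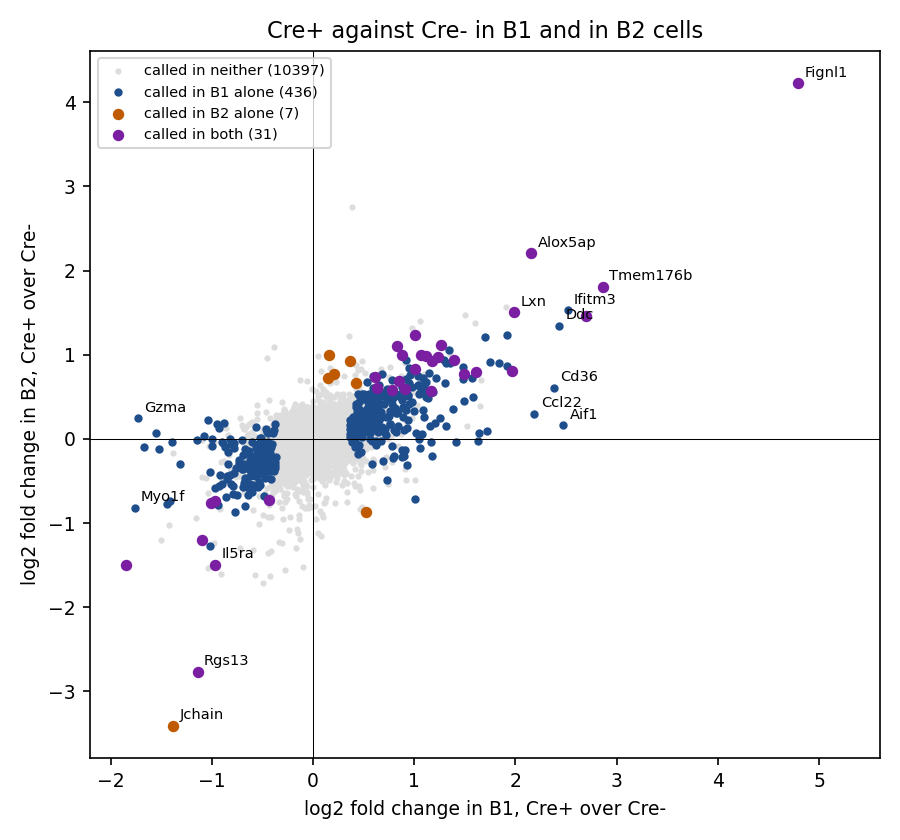
Log2 fold change of Cre+ over Cre- in B1 cells (horizontal axis) and in B2 cells (vertical axis) for the 10871 tested genes, coloured by where limma called them at an adjusted p below 0.05. The 31 genes called in both lie on the same side of zero in each, with Fignl1 at 4.80 and 4.23.

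**Figure D3:**
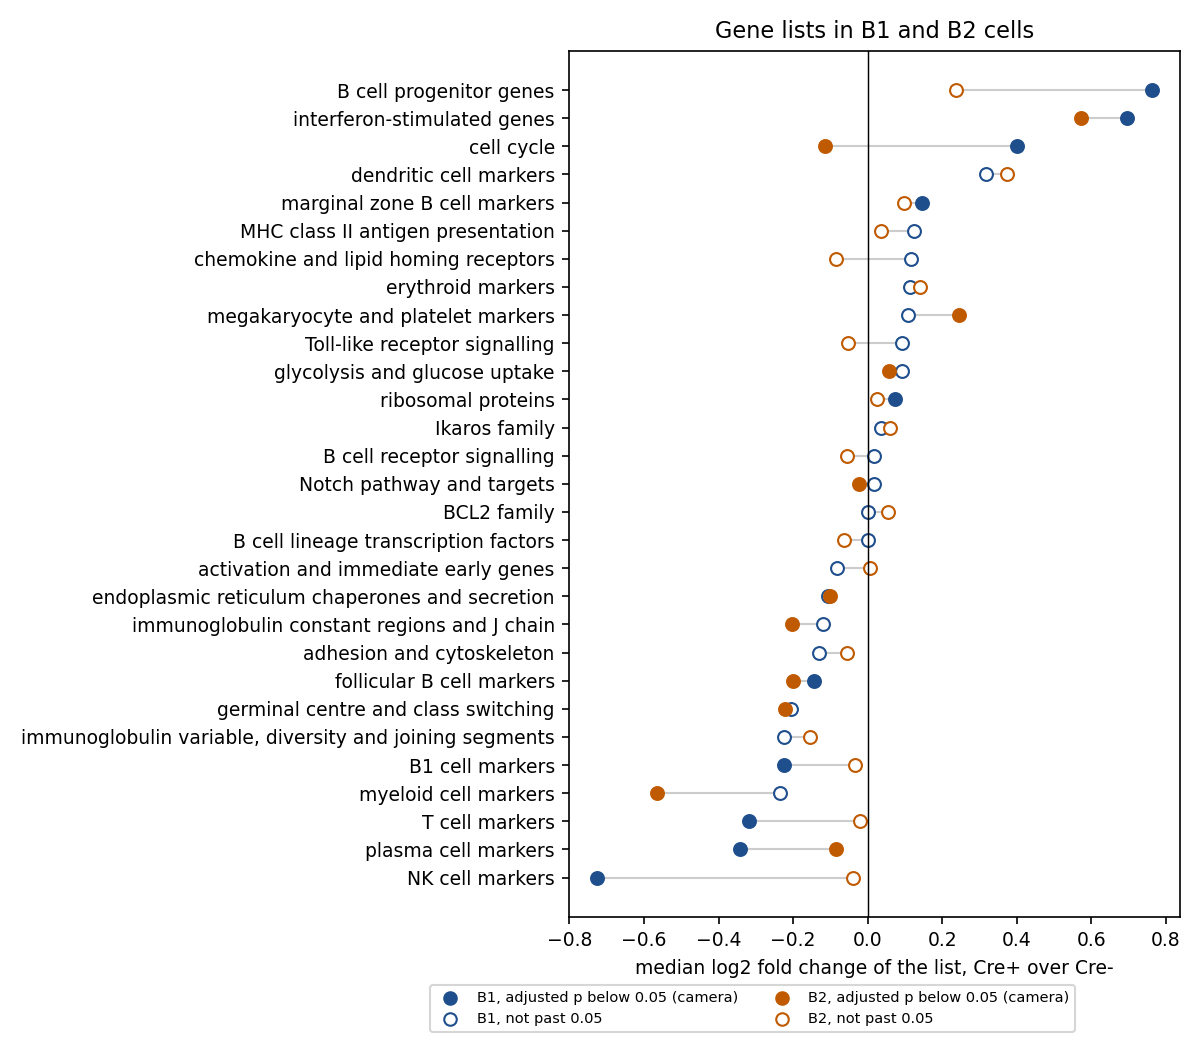
Median log2 fold change of Cre+ over Cre- (horizontal axis) for the members of 29 gene lists in B1 cells (blue) and B2 cells (orange), with filled points where camera with a preset correlation gave an adjusted p below 0.05. Interferon-stimulated genes lie at 0.70 and 0.57, cell cycle genes at 0.40 and -0.12, and T cell markers at -0.32 and -0.02; with an estimated correlation no point would be filled.

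Averaged over both cell types, with 4 arrays per arm, Fignl1 rose by 4.51 (SE 0.19), Tmem176b by 2.33 (SE 0.21), Alox5ap by 2.18 (SE 0.16) and Tmem176a by at least 2.08 (SE 0.22). Rgs13 fell by at least 1.95 (SE 0.32) and Myo1f by 1.29 (SE 0.19). The lymphocyte adapter genes Sh2d1b1 and Fyb fell by at least 1.28 (SE 0.28; to 4.49 in B1 and 4.25 in B2) and by 1.26 (SE 0.30). Interferon-stimulated genes had a median of 0.65 (adjusted p = 2.3e-13, adjusted p = 0.381 with an estimated correlation), 0.28 and 1.05 by experiment, with 10 of 23 called higher and 16 adjusted over the list alone. Among these Ifih1 rose by 0.97 (SE 0.15). Plasma cell markers had a median of -0.24 (adjusted p = 0.000148, adjusted p = 0.381 with an estimated correlation), with 6 of 18 called lower, and 2 higher and 8 lower adjusted over the list alone; Txndc5, a folding enzyme, fell by 0.61 (SE 0.08). Progenitor genes had a median of 0.50 (adjusted p = 0.00288, adjusted p = 0.381 with an estimated correlation), with 2 of 10 called and 6 adjusted over the list alone. MHC class II genes had a median of 0.08 (adjusted p = 0.0308, adjusted p = 0.517 with an estimated correlation), with 2 of 14 called and 2 adjusted over the list alone, 0.12 and 0.06 by experiment. Their call was lost with quantile normalization applied again (adjusted p = 0.0819) and without Cre+ B1 replicate 1 (0.0929, median 0.05), Cre+ B2 replicate 1 (0.0711) or Cre- B1 replicate 2 (0.0754). Immunoglobulin variable, diversity and joining segments had a median of -0.15 (adjusted p = 0.0374, adjusted p = 0.381 with an estimated correlation), with 0 of 8 called by limma, 3 at an unadjusted p below 0.05, and 2 lower adjusted over the list alone. The segment call was lost without Cre+ B1 replicate 1 (adjusted p = 0.0929), Cre+ B2 replicate 1 (0.0711) or Cre- B2 replicate 1 or 2 (0.0504 and 0.0689).

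Markers of other cells moved with the averaged effect, to which 12 of 20 T cell and 4 of 7 NK cell markers at or below 5.02 in both B2 groups gave no measured B2 part. T cell markers fell with a median of -0.16 (adjusted p = 0.000182, adjusted p = 0.381 with an estimated correlation), -0.21 and -0.23 by experiment, with 2 of 20 called lower and 4 adjusted over the list alone. Megakaryocyte and platelet markers rose with a median of 0.18 (adjusted p = 0.00330, adjusted p = 0.381 with an estimated correlation), 0.21 and 0.15 by experiment, with 2 of 6 called and 4 adjusted over the list alone. Pf4, a platelet chemokine, rose by at least 1.15 (SE 0.17). NK cell markers fell with a median of -0.30 (adjusted p = 0.0352, adjusted p = 0.381 with an estimated correlation), with 0 of 7 called by limma, 3 at an unadjusted p below 0.05, and 0 adjusted over the list alone. Their call was lost without Cre+ B1 replicate 1 or 2 (adjusted p = 0.130 and 0.0685) or Cre- B1 replicate 2 (0.134). Myeloid markers fell with a median of -0.42 (adjusted p = 0.0374, adjusted p = 0.381 with an estimated correlation), -0.51 and -0.22 by experiment, with 0 of 17 called by limma, 3 at an unadjusted p below 0.05, and 0 adjusted over the list alone. The myeloid call was lost with quantile normalization applied again (adjusted p = 0.0502) and without Cre+ B1 replicate 1 (0.109), Cre- B1 replicate 2 (0.134), Cre+ B2 replicate 1 (0.101, median -0.13) or Cre- B2 replicate 1 or 2 (0.0504 and 0.0786, the latter with a median of -0.25). The median was -0.62 without Cre- B1 replicate 1.

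Several lists did not pass in the averaged effect. B cell receptor signalling had a median of -0.03 (adjusted p = 0.434, 2 of 28 called lower, 2 higher and 3 lower adjusted over the list alone). Activation and immediate early genes had a median of -0.04 (adjusted p = 0.327, 2 of 22 called lower, the same number adjusted over the list alone). The BCL2 family had a median of 0.05 (adjusted p = 0.166, 2 of 13 called higher, 2 adjusted over the list alone). Adhesion and cytoskeleton genes had a median of -0.14 and a mean of 0.00 (adjusted p = 0.434, 5 of 23 called higher and 5 lower, 6 and 9 adjusted over the list alone), and Ctnnd1, a catenin that stabilizes cadherins, rose by at least 1.45 (SE 0.16; 4.96 in Cre- B1). B cell lineage transcription factors had a median of -0.04 (adjusted p = 0.545, 3 of 23 called higher and 2 lower, 4 and 4 adjusted over the list alone), and Id3, an inhibitor of E proteins, fell by 0.68 (SE 0.11). Toll-like receptor signalling had a median of 0.01 (adjusted p = 0.261, 2 of 24 called higher, 6 higher and 1 lower adjusted over the list alone). Chemokine and lipid homing receptors had a median of 0.03 (adjusted p = 0.441, 1 of 16 called and 2 adjusted over the list alone). Gpr183, a receptor that guides B cells in follicles, rose by 0.54 (SE 0.08). Dendritic markers had a median of 0.35 (adjusted p = 0.0868, 3 of 6 called higher, 3 higher and 1 lower adjusted over the list alone). The Ikaros family had a median of 0.05 (adjusted p = 0.101), with Ikzf1 called of 4, also adjusted over the list alone. In limma 544 genes passed, 318 higher and 226 lower, 50 of them more than 2-fold, and 309 features with all probe sets. The differences of the experiments correlated at 0.641 across genes. Without Cre- B1 replicate 1 or 2 the count was 224 or 280, without Cre- B2 replicate 1 it was 283 and without Cre+ B1 replicate 2 it was 327. Sh2d1b1 and Fyb both lost their calls without Cre- B1 replicate 1 (adjusted p = 0.110 and 0.118) or 2 (0.0646 and 0.0916), Cre- B2 replicate 1 (0.0955 and 0.102) or 2 (0.0916 and 0.119) or Cre+ B1 replicate 2 (0.0912 and 0.0618), and Fyb also without Cre+ B1 replicate 1 (0.103).

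The interaction asked which deletion effects differ between B1 and B2 cells. The measured effect on Ccl22 was higher in B1 than in B2 cells by 1.89 (SE 0.20, adjusted p = 0.0452). For Shtn1, which guides axon growth, it was higher by 1.57 (SE 0.14, adjusted p = 0.0246), Nrp1, a co-receptor for semaphorins and VEGF, by 1.16 (SE 0.11, adjusted p = 0.0329), and Socs2, an inhibitor of cytokine signalling, by 1.63 (SE 0.18, adjusted p = 0.0479). A second probe set of Socs2 gave 0.31. In B2 cells none of the 4 genes exceeded 5.02 in either group: with and without Cre, Ccl22 lay at 4.94 and 4.64, Shtn1 at 4.39 and 4.32, Nrp1 at 4.45 and 4.30 and Socs2 at 4.51 and 4.41. Shtn1, Nrp1 and Socs2 lay below it in Cre- B1 as well (4.53, 4.54 and 4.51). Their effects in B2 were therefore not measured, and the sizes of these interactions are neither exact nor bounds. Differences that did not pass were -1.62 for Dapl1 (adjusted p = 0.0735), -1.36 for Parm1 (adjusted p = 0.0735; with the replicate as a block 0.0315), -1.12 for Prkcq (adjusted p = 0.100) and -1.11 for Tmc3 (adjusted p = 0.0725). Dapl1, Prkcq and Tmc3 lay below 5.02 in both B2 groups, so these sizes are not exact either. Of the gene lists the cell cycle differed by a median of 0.45 (adjusted p = 5.7e-14, adjusted p = 0.426 with an estimated correlation), 0.46 and 0.36 by experiment, with 0 of 31 called by limma, 17 at an unadjusted p below 0.05, and 12 adjusted over the list alone. T and NK cell markers differed by medians of -0.31 and -0.62 (adjusted p = 8.4e-10 and 1.6e-05, adjusted p = 0.341 and 0.344 with an estimated correlation). In both B2 groups 12 of the 20 T cell markers and 4 of the 7 NK cell markers lay at or below 5.02, where a fall could not be measured. These values therefore do not show that the response differed between the cell types, and the other 8 T cell markers had a median of -0.19. The NK median was -0.99 without Cre- B1 replicate 1 and -0.98 without Cre+ B1 replicate 2. Myeloid markers, with a median of 0.35 (adjusted p = 0.416), passed with the replicate as a block (adjusted p = 0.0250). In all 4 genes passed in limma, 738 at an unadjusted p below 0.05, and 8 with the replicate as a block. The count was 8 without Cre+ B1 replicate 1, 7 without Cre+ B2 replicate 2, 1 without Cre+ B2 or Cre- B1 replicate 1, and 0 without Cre- B2 replicate 1 or 2, Cre+ B1 replicate 2 or Cre- B1 replicate 2 (493, 496, 1291 and 580 at an unadjusted p below 0.05), so none of the 4 genes passed in all of these. Dapl1 passed without Cre- B1 replicate 1 (adjusted p = 0.0453), and Parm1 and Tmc3 without Cre+ B1 replicate 1 (0.0455 each).

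The next comparison set control B1 cells against control B2 cells. Expression in the B cells and in T cells, NK cells or macrophages admixed to a sort cannot be told apart here. The differences and gene counts between B1 and B2, here and after deletion, may include both. T cell genes were higher in B1 cells: Cd3g by at least 5.10 (SE 0.14), Thy1 by 4.34 (SE 0.13) and Cd3d by at least 4.17 (SE 0.14), with n = 2 per group. Cytotoxic lymphocyte genes were higher too, Gzma by at least 4.08 (SE 0.30), Nkg7 by at least 3.64 (SE 0.24) and the chemokine gene Ccl5 by 3.63 (SE 0.25), as were Adm, which encodes the vasoactive peptide adrenomedullin, by at least 4.05 (SE 0.33), and Emb, a transmembrane glycoprotein, by 3.83 (SE 0.15). In control B2 cells Cd3g (3.89) and Gzma (3.87) lay near the lower quartile of the arrays, at 3.88 to 3.92. Cd3d (4.46), Nkg7 (4.40) and Adm (4.69) lay below the array medians. All 20 T cell markers were called higher, with a median of 2.12 (adjusted p = 1.5e-145, adjusted p = 0.0239 with an estimated correlation), 2.33 and 1.62 by experiment, and 20 adjusted over the list alone. NK cell markers had a median of 2.82 (adjusted p = 9.8e-19, adjusted p = 0.0742 with an estimated correlation), with 5 of 7 called and 5 adjusted over the list alone. Lower in B1 cells were Spic, a transcription factor of red pulp macrophages, by -3.48 (SE 0.78), the iron exporter Slc40a1 by -3.36 (SE 0.65), the haem-degrading enzyme Hmox1 by -3.08 (SE 0.72) and the adhesion molecule Vcam1 by -2.95 (SE 0.67). The complement genes C1qa (-3.13, SE 0.68) and C1qc (-3.03, SE 0.68), Adgre4 (-3.12, SE 0.61) and Ccr3 (-3.10, SE 0.66) were lower as well. These 8 genes with lower values were not called without Cre- B1 replicate 1 or 2 or Cre- B2 replicate 1 or 2, with adjusted p values from 0.0643 for C1qc to 0.188 for Hmox1. Myeloid markers had a median of -1.43 (adjusted p = 0.00296, adjusted p = 0.425 with an estimated correlation), with 10 of 17 called lower and 2 higher, and 11 and 4 adjusted over the list alone; the call was lost without Cre- B1 replicate 1 (adjusted p = 0.170). Erythroid markers were lower with a median of -0.35 (adjusted p = 0.0378, adjusted p = 0.371 with an estimated correlation), with 2 of 4 called, also adjusted over the list alone, and lost the call without either Cre+ B1 array (adjusted p = 0.0514), Cre- B1 replicate 1 (0.170) or Cre- B2 replicate 2 (0.148).

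Markers of the B cell subsets separated in control cells. B1 cell markers were higher in B1 with a median of 1.70 (adjusted p = 3.8e-44, adjusted p = 0.0767 with an estimated correlation), 1.64 and 1.54 by experiment. Of 22 members 17 were called higher and 1 lower, and 19 and 1 adjusted over the list alone. The transcription factor genes Zbtb32 and Bhlhe41 differed by 3.17 (SE 0.26) and 2.83 (SE 0.25), and Cd5, a brake on receptor signalling, by 2.77 (SE 0.21). This list holds Spn, whose protein CD43 was used for the sort, and Ctla4, which is also a listed T cell marker. Part of its separation, here and after deletion, may therefore come from the sort or from the T cell signal on the B1 arrays. Plasma cell markers were higher with a median of 0.66 (adjusted p = 3.4e-15, adjusted p = 0.0727 with an estimated correlation), 13 of 18 called and 15 adjusted over the list alone, among them Jchain by 2.97 (SE 0.38) and Prdm1 by at least 1.43 (SE 0.14; 4.66 in Cre- B2). Chaperones of secretion were higher with a median of 0.21 (adjusted p = 0.000617, adjusted p = 0.135 with an estimated correlation), 6 of 25 called and 9 adjusted over the list alone. Immunoglobulin constant regions had a median of 0.79 (adjusted p = 6.7e-05, adjusted p = 0.0742 with an estimated correlation) with 3 of 4 called, and variable segments 0.77 (adjusted p = 1.8e-07, adjusted p = 0.0618 with an estimated correlation) with 5 of 8 called, 3 and 6 adjusted over the list alone. Adhesion genes were higher with a median of 0.26 (adjusted p = 5.9e-05, adjusted p = 0.170 with an estimated correlation), with 8 of 23 called higher and 1 lower, 12 and 3 adjusted over the list alone, including the integrin gene Itgb1 by 1.67 (SE 0.12). Follicular markers were lower in B1 with a median of -0.48 (adjusted p = 8.6e-12, adjusted p = 0.0742 with an estimated correlation), -0.42 and -0.54 by experiment, with 9 of 15 called and 12 adjusted over the list alone. Complement receptor 2 (Cr2) was lower by -1.46 (SE 0.17) and Fcer2a by -1.37 (SE 0.08). B cell lineage transcription factors were lower with a median of -0.26 (adjusted p = 5.2e-06, adjusted p = 0.0618 with an estimated correlation), 11 of 23 called lower and 1 higher, the same numbers adjusted over the list alone. Toll-like receptor signalling was lower with a median of -0.11 (adjusted p = 0.00675, adjusted p = 0.170 with an estimated correlation), with 6 of 24 called lower and 6 adjusted over the list alone. Germinal centre genes (median -0.20, adjusted p = 0.0400, 0.425 with an estimated correlation) and MHC class II genes (median -0.30, adjusted p = 0.0112, 0.425 with an estimated correlation) lost their calls with the replicate as a block (adjusted p = 0.0788 and 0.265), the former also without either Cre+ B1 array (0.247) or Cre- B1 replicate 2 (0.0941). The germinal centre medians were -0.12 and -0.08 without Cre- B2 replicate 1 and 2. Of 11 and 14 members 1 each was called higher, and 2 and 5 lower, with 1 each and 4 and 8 adjusted over the list alone. Bcl6, the germinal centre regulator, was lower by -1.83 (SE 0.15). In limma 957 genes differed, 513 higher and 444 lower in B1, and the differences of the experiments correlated at 0.851 across genes. Without Cre- B1 replicate 1 or 2 the count was 409 or 377, and without Cre- B2 replicate 1 or 2 it was 354 or 308.

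After deletion the subsets were compared in the same way. Jchain was higher in B1 than in B2 cells by at least 4.999 (SE 0.38, n = 2 per group), Cd3g by at least 4.04 (SE 0.14), Cd3d by at least 3.86 (SE 0.14) and Thy1 by 3.71 (SE 0.13). Cpm, a carboxypeptidase, was lower by -2.27 (SE 0.23), Pxdc1 by -2.08 (SE 0.12), Fcer2a by -1.99 (SE 0.08) and Icosl, the ligand of the T cell costimulator ICOS, by -1.73 (SE 0.11). In Cre+ B2 cells Jchain lay at 4.98, Cd3g at 4.01 and Cd3d at 4.44. All 8 had adjusted p values below 0.001 and were called whichever array was left out. T cell markers were higher with a median of 1.44 (adjusted p = 4.7e-115, adjusted p = 0.0311 with an estimated correlation), 18 of 20 called and 19 adjusted over the list alone, and NK cell markers with a median of 2.10 (adjusted p = 2.5e-09, adjusted p = 0.109 with an estimated correlation), 4 of 7 called and 5 adjusted over the list alone. B1 cell markers were higher with a median of 1.38 (adjusted p = 2.1e-42, adjusted p = 0.0859 with an estimated correlation), 18 of 22 called, and 19 higher and 1 lower adjusted over the list alone. Follicular markers were lower with a median of -0.36 (adjusted p = 7.1e-14, adjusted p = 0.0859 with an estimated correlation), 7 of 15 called and 10 adjusted over the list alone. Cell cycle genes were higher in deleted B1 cells with a median of 0.54 (adjusted p = 2.1e-10, adjusted p = 0.236 with an estimated correlation), 0.37 and 0.65 by experiment, with 9 of 31 called and 18 adjusted over the list alone. In control cells this list had a median of -0.06, a mean of -0.01 and a test direction of up (adjusted p = 0.723). Progenitor genes were higher with a median of 0.50 (adjusted p = 0.000148, adjusted p = 0.282 with an estimated correlation), with 3 of 10 called, and 5 higher and 2 lower adjusted over the list alone. Their medians were 0.56 and 0.36 by experiment, and 0.24 without Cre+ B1 replicate 1 with the call kept. Myeloid markers had a median of -0.49 (adjusted p = 0.0211, adjusted p = 0.472 with an estimated correlation), -0.13 and -1.02 by experiment, with 0 of 17 called by limma, 6 at an unadjusted p below 0.05, and 2 lower adjusted over the list alone. That call was lost without Cre+ B1 replicate 1 (adjusted p = 0.102) or Cre+ B2 replicate 2 (adjusted p = 0.130, median -0.10). The median was -1.04 without Cre+ B2 replicate 1. In limma 610 genes differed, 425 higher and 185 lower, and 366 without Cre+ B1 replicate 1 or 297 without Cre+ B2 replicate 2. With control cells 280 genes were shared in the higher direction (20.1 by independent draws), 130 in the lower (7.56), and 1 was opposite. The estimate of spread was shared here too, so independent draws can understate this overlap.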

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

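The tests of explanations in this part were chosen only after the results they concern were seen, except the test of other splits of the arrays, and so were the neighbours and markers named with them.

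Genes whose deletion effect differed between B1 and B2 cells were marked as differences between groups. Ccl22, a chemokine for CCR4-bearing T cells, differed by a log2 value of 1.89 (SE 0.20), Socs2, an inhibitor of cytokine signalling, by 1.63 (SE 0.18), Shtn1 by 1.57 (SE 0.14) and Nrp1, a co-receptor for semaphorins, by 1.16 (SE 0.11), each higher in B1 and with adjusted p values in limma from 0.0246 to 0.0479; all 4 lay at 4.94 or lower in both B2 groups, at or below the array medians, so these sizes are not exact. Among gene lists the cell cycle differed by a median of 0.45, with adjusted p = 0.426 with an estimated correlation. B cell progenitor genes differed by 0.39 (adjusted p = 0.000560; without Cre- B1 replicate 1 0.0614, without Cre+ B2 replicate 2 0.0894; adjusted p = 0.398 with an estimated correlation) and were at 0.61 and 0.16 by experiment, at 0.14 or 0.65 without Cre+ B1 replicate 1 or 2, and at 0.60 without Cre- B1 replicate 2. Germinal centre genes differed by 0.18 (adjusted p = 0.00244; without Cre+ B1 replicate 1 0.102; adjusted p = 0.426 with an estimated correlation), and by 0.38 without Cre- B1 replicate 1 or 0.28 without Cre+ B1 replicate 2. Marginal zone markers differed by 0.12 (adjusted p = 0.00370, adjusted p = 0.426 with an estimated correlation), at -0.05 and 0.28 by experiment. That call was lost without Cre- B1 replicate 1 (0.0569), Cre+ B1 replicate 2 (0.114, median 0.05) or Cre- B2 replicate 2 (0.0735), and the median was 0.23 without Cre+ B1 replicate 1 and 0.23 or 0.08 without Cre+ B2 replicate 1 or 2. Toll-like receptor signalling differed by 0.088 (adjusted p = 0.00370, adjusted p = 0.344 with an estimated correlation; 0.20 without Cre- B1 replicate 1 and 0.18 without Cre+ B1 replicate 2), T cell markers by -0.31 (adjusted p = 0.341 with an estimated correlation) and NK cell markers by -0.62 (adjusted p = 0.344 with an estimated correlation), though 12 of 20 and 4 of 7 of these lay at or below 5.02 in both B2 groups, where no fall could be measured; 3 of 10 progenitor and 3 of 31 cell cycle genes did so too. Probe sets with no gene or several genes were data without a report: of 6736 tested among all probe sets, 8 were called higher and 10 lower in Cre+ B1 cells.

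Fignl1 and Ddc, a DNA repair gene and a decarboxylase gene beside Ikzf1, rose on the arrays labelled Cre+ with averaged log2 changes of 4.51 and at least 1.89. A change at the locus that reaches only that side would call higher the nearest genes there and none on the other side. Of the 3 nearest genes 2 were called higher on the Fignl1 side, with Grb10 at -0.02, but 1 was called on the other side, Zpbp at -0.43 (adjusted p = 0.00910), a dim gene that fell from 4.85 to 4.42. The prediction was not met because of Zpbp. Zpbp lay below 5.02 with and without Cre, as did Spata48 (4.82 and 4.87), 4930512M02Rik (3.97 and 3.92) and Grb10 (3.89 and 3.92). The rises of Fignl1 and Ddc had prompted the test. It thus rests on genes not clearly above background and cannot decide the question. An effect in cis and an effect of lost Ikaros binding both stay open. More cycling cells would raise the cell cycle genes with Fignl1, but in B2 cells their upper quartile was -0.042 and their median -0.12 while Fignl1 rose by 4.23.

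T and NK cell markers were lower in Cre+ B1 cells, as Cd3g showed with a fall from 8.99 to 8.05. A lower share of T and NK cells in the sort by 1 common factor would lower T cell markers alike. This holds only if each marker's signal comes from those cells alone and scales alike with their share. All 10 T cell markers at least 4-fold higher in control B1 than B2 cells were lower, by -0.05 (Cd8a) to -1.03 (Cd28), around a common -0.54. In a test against simulated errors these falls were unequal across genes (n = 10 markers, which are not independent replicates; simulated p = 0.0057). Neither condition on the signals was tested, so the unequal falls do not exclude a common factor. The 10 markers were chosen by their level in control B1 cells, which is also the baseline of these falls. That all 10 were lower may partly reflect this choice. A gate on CD19 is meant to remove T cells. A lower share of admixed T cells, a change in their makeup and lower transcription in the B1 cells themselves all stay open.

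Tmem176a, Tmem176b, Aif1, Cd36 and Ccl22, known from myeloid and dendritic cells, rose in Cre+ B1 cells by a median log2 change of 2.47. Cd36 is also a listed marginal zone marker, and that list rose in Cre+ B1 cells as well. More myeloid cells in the sort would raise myeloid markers as a group, but their upper quartile was 0.070. More dendritic cells would raise all dendritic markers, and by more than 2 standard errors 2 were lower (Cox6a2 at -0.45, adjusted p = 0.0720; Batf3 at -0.23, 0.239) and 3 higher (Siglech at 1.49, 0.0105; Flt3 at 0.76, 0.172; Bst2 at 0.46, 0.132). Bst2 is also a listed interferon-stimulated gene, and that list rose too. Only Siglech of these dendritic markers passed, so the bound of 2 standard errors was too loose to exclude dendritic cells. More myeloid cells with their usual markers would not give this rise, while more dendritic cells and a change in the B1 cells themselves stay open.

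The averaged deletion effect called 544 genes. Of the 34 splits of the 8 arrays into 4 and 4 that could be fitted, 1 called as many, the real grouping itself, and the highest count of another split was 5, for the split by replicate number. Of these 17 take 2 arrays from each experiment, and the highest count of another split among them was 0 genes in limma. The other 17 mix the experiments unevenly. Every split but the real one mixes Cre+ and Cre- arrays and leaves the Cre difference in the residuals, which lowers its count. Among the even splits the real one can be at best 1 of 17. These counts therefore cannot exclude chance.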

How the results depend on the processing

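No alternative was chosen after the results were seen. Among the 511 gene results and 73 list results followed, no call turned to the opposite direction under the alternatives run, though the medians of the cell cycle and Notch lists in B2 and of Notch in the averaged effect changed sign without 1 array. Of 5440 tests of 511 gene results under settings that kept all arrays 5087 kept their side of the threshold, and so did 3523 of 4088 without 1 array. For 73 list results these counts were 770 of 934 and 510 of 584. With all probe sets, named or not, limma called 125 features for deletion in B1, 0 in B2 (1498 at an unadjusted p below 0.05), 0 for the interaction (1184) and 309 for the averaged deletion. That fit covers 18730 features with 2.41 prior degrees of freedom in place of 4.24. Ikzf1 in B1, at 0.67, had an adjusted p of 0.0733 there and of 0.0592 with only the 4 arrays of the groups compared. With only those 4 arrays, hence fewer residual degrees of freedom, 234 genes were called in B1 and 261 between deleted B1 and B2. Array weights gave 251 genes in B1 and 157 in B2, and Ikzf1 in B2, at 0.51, passed (adjusted p = 0.0395). Both arrays of a group had the same weight: 0.65 in Cre+ B1, 0.95 in Cre- B1, 1.01 in Cre+ B2 and 1.61 in Cre- B2. The weights thus let the spread differ between groups, while the main fit takes it as equal. The main counts, 467 in B1 and 38 in B2, depend on that assumption. In B2 a variance prior with trend gave 69, a robust prior 72 and the replicate block 91. For the interaction no filter gave 2, a filter at the 75th percentile 0 (390 at an unadjusted p below 0.05), arrays centred on their median 11, a robust prior 15 and the replicate block 8. The cause was not tested for the priors, block and centring. Lists called with a filter at the 75th percentile, which tests fewer genes, were 5 for deletion in B1, 6 in B2, 4 for the interaction and 5 averaged. With an inter-gene correlation estimated from the residuals they were 0, 0, 0 and 0, and 1 each for control and deleted B1 against B2; with fry they were 4, 1, 0 and 8. Without 1 array the called genes ranged from 109 to 390 for deletion in B1, from 1 to 78 in B2, from 308 to 1096 for control and from 297 to 761 for deleted B1 against B2, from 0 to 8 for the interaction and from 224 to 523 averaged. Lists ranged from 6 to 12 for deletion in B2, and Ikzf1 in B1 from 0.51 to 0.84. Signal over background could not be set against calls, as detection calls were not used here.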

Other observations

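The genes in this part were chosen after their values were seen, and no test was run on a hypothesis of its own.

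Further genes called in both cell types rose in B1 and B2 cells. These were Alox5ap, needed for leukotriene synthesis, at 2.16 and 2.21 (SE 0.23), the carboxypeptidase inhibitor gene Lxn at 1.99 and 1.51 (SE 0.20), Ptgr1, which inactivates leukotriene B4 and prostaglandins, at 1.97 and 0.81, and Serpinb6b, an inhibitor of granzyme, at 1.39 and 0.93. Gna15, a G protein subunit of blood cells, rose by at least 1.06 and by 1.00, Ebi3, a subunit of immunoregulatory interleukins, by 0.88 and 1.00, and Nbn, which senses DNA double-strand breaks, by 0.78 and 0.58. Pirb, an inhibitory receptor for MHC class I, fell by 1.09 and 1.20 (SE 0.14), Tmem71 by 1.01 and 0.76 (SE 0.10) and Endou by 0.96 and at least 0.74 (SE 0.10). All had adjusted p values below 0.05 in limma in both cell types, with 2 arrays per group.

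Genes called in B2 cells and not called in B1 numbered 7, and none of them passed in the interaction, where adjusted p in limma was 0.0725 for Ms4a7 and 0.445 for Jchain. Csf2rb, a receptor chain shared by GM-CSF and related cytokines, rose by 1.00, the aryl hydrocarbon receptor gene Ahr by 0.78, Ms4a6b by 0.93, Tmem154 by 0.72 and Socs3, an inhibitor of cytokine signalling, by 0.66. Jchain fell by at least 3.41 in B2 and differed by -1.38 in B1 (adjusted p = 0.0902 in limma; 0.0303 with the replicate as a block), and Ms4a7 fell by 0.87 in B2 while it differed by 0.52 in B1 (adjusted p = 0.0585 in limma).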
